A study of Arabidopsis thaliana with 6 samples.

How the data were processed

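Whole 5-day-old Arabidopsis seedlings of 3 genotypes, grown under a light-dark cycle with no treatment, were profiled on 6 Affymetrix arrays (ATH1, the platform of the probe annotation), with 2 biological replicates per genotype per the labels. The genotypes were the wild type, a line labelled as an atvap mutant, and the wild type carrying an overexpressed TaVAP (TaVAPOE). The labels state neither the locus of the mutation nor the accession of the lines.

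The deposited values are probe-set scores on a log scale whose base is not stated, for 22810 probe sets, with medians per array between 2.74 and 2.88 and maxima between 10.5 and 11.2. The submitters' processing notes name Agilent Feature Extraction, with no version, which does not go with an Affymetrix array, and the summarisation and normalization are not given in the sources used here. The value 10.7 of the brightest probe set recurs exactly on 3 arrays. Values were kept as deposited. The design kept log values as they stand if they had been normalized between arrays, which the sources do not state and which the spread of the 99th percentiles (4.88 to 7.80) leaves in doubt, so quantile normalization was run as an alternative. Differences are given in log units of the deposited scale, and folds are given for base 2, the smaller of the readings considered, since a natural log would give larger folds. The fixed design spoke of log2 values. The limma test used here does not depend on the base, but the setting that adds 16 on the linear scale and the 2-fold threshold (1 log unit) assume base 2.

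The 64 control probe sets were left out of the tests, and 22746 were tested. Gene names came from the platform annotation through Entrez identifiers and the RefSeq gene table of the TAIR10.1 assembly. Of the probe sets tested, 13513 have 1 gene in that annotation, 503 have several and 8730 are unnamed here; 13436 of those with 1 gene were matched to the RefSeq table. Where a gene had several probe sets, the one with the highest mean over the 6 arrays was taken, which left 13356 genes.

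Each comparison was a contrast in 1 limma fit (version 3.58.1, R 4.3.3) over all 6 arrays, with a mean per genotype, 3 residual degrees of freedom, no block, and Benjamini-Hochberg adjustment at 0.05 within the comparison. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. There were 27 lists with 454 distinct genes, of which 69 genes had a probe set with 1 gene. Only 6 lists held at least 5 measured genes and were tested: the VAP27 family, heat shock, cold response, endoplasmic reticulum (ER) stress, photosynthesis and auxin. For 6 other lists, among them abscisic acid and drought, no member was analysed here. Where a gene is said to pass adjusted over the list alone, its p was adjusted only over the measured genes of that list in that comparison. It was not adjusted over the lists or the comparisons, so such a pass is weak, above all for short lists. Errors given with ± are limma's moderated standard errors.

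Named genes followed a rule fixed before the data were examined. It took all measured VAP27 family members, and the genes with the largest differences in each direction among those past the threshold with non-overlapping groups and a mean above the median. Where too few passed, up to 5 per direction were filled in at an unadjusted p under 0.01. It also took up to 4 members, those with the smallest p, of each called list and of the stress lists. A fit to 4 arrays, leaving aside wild-type replicate 1 and mutant replicate 1, was added after the correlations and control probe sets of the arrays had been seen. It has 1 residual degree of freedom, from the TaVAPOE pair, so the single wild-type and mutant arrays are assumed to vary as that pair does. Up to 10 genes per direction with an unadjusted p under 0.01 in it were listed by the same conditions, and those the text names from that fit were chosen after their values were seen. Array quality weights in limma were also added then, and later the 4-array fit with values raised to the 20th percentile, with camera at an estimated correlation and with fry, and camera at an estimated correlation in the fits that leave out 1 array, in the fit to the 2 groups and with the weights. Where a genotype read below 1.66, the 20th percentile of all values, on every array used, the difference with values raised to 1.66 is given as a lower bound on its size for the larger differences. That percentile stands in for a background level, since no detection calls were used here.

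The alternatives fixed beforehand were a filter on probe sets below the 40th percentile, quantile normalization, median centring, the replicate number as a block, a fit to the 2 groups alone, an intensity trend with robust moderation, a floor at the 20th percentile, the added 16, removal of probe sets that match several transcripts, leaving out each array, and other thresholds. The correlation between the 2 lines' differences from the wild type was set against 100 simulations of unchanged groups sharing the same wild-type arrays.

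The procedure was tested on simulated data for 22746 probe sets, with variances drawn from the fitted prior, and with 67 probe sets changed by 1 log unit, 67 by 2 and 66 by 4. For TaVAPOE against wild type, the 6-array fit recovered 0% of changes of 4 log units. For that comparison the 4-array fit recovered 97.0% of changes of 4 log units, 53.7% of 2 and 0% of 1, and 16 of its 116 calls were false. For TaVAPOE against mutant 9 of 115 calls of the 4-array fit were false, and for mutant against wild type 3 of 63. This simulation replaced an earlier one that took each probe set's posterior variance as its true variance, in which 81 of 268, 32 of 206 and 45 of 207 calls of the 4-array fit were false in the same order of comparisons. In both, the share of false calls for TaVAPOE against wild type and against mutant lay above the nominal 5%. The calls of the 4-array fit are thus less certain than their adjusted p. Both simulations gave the single wild-type and mutant arrays of that fit the spread of the TaVAPOE pair, so neither covers a wider one. Camera called a list shifted by 2 log units in 100 of 100 simulated data sets, and 1.6% of unshifted lists. The simulated genes varied independently, and all arrays had the same spread. That rate thus does not cover lists whose members move together on a discordant array. The number of arrays limits the precision. The p-values measure the spread between arrays that the labels call biological replicates. In the 4-array fit that spread comes from the TaVAPOE pair alone, in every comparison.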

Results

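Expression was measured in whole 5-day-old light-grown Arabidopsis seedlings of 3 genotypes, with 2 arrays each. VAP proteins (VAP27 in plants) sit in the ER membrane and tether it to other membranes, and the Ta prefix is that of wheat genes. By its title the series asked what TaVAP does in stress tolerance, so the design compares the atvap mutant and the TaVAPOE line with the wild type and with each other. The transgene itself was not analysed here.

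All 5 measured genes of the photosynthesis list read lowest on mutant replicate 1, and some of them were also low on wild-type replicate 1. LHCB4.1, an antenna protein of photosystem II, read 9.09 and 9.22 log units on the wild-type arrays, 9.02 on mutant replicate 2 and 9.29 and 9.11 on the TaVAPOE arrays, but 2.62 on mutant replicate 1. Rubisco activase (RCA) read 4.07 there against 8.92 to 9.55 on the other 5 arrays. LHCB4.2 read 2.32 there and 3.94 on wild-type replicate 1, against 6.34 to 7.61 on the other 4 arrays. Plastid-encoded transcripts differed in this, in 2 examples chosen after their values were seen: psaB read 3.45 and 6.18 on these arrays against 8.23 to 8.95 on the others, while psbM read 9.05 on mutant replicate 1 and 8.98 to 9.70 on the other 5. Plant reference genes (actin, GAPDH and ubiquitin, 6 probe sets near the 3' end) averaged 3.503 on mutant replicate 1, 6.09 on wild-type replicate 1, and 7.54 to 7.65 on the other 4 arrays. Across 22746 probe sets, these 4 arrays correlated with each other at Pearson r from 0.94 to 0.98. Wild-type replicate 1 reached only 0.52 to 0.53 with them, and mutant replicate 1 at most 0.19 with any array. The replicates of TaVAPOE correlated at 0.98, those of the wild type at 0.52 and those of the mutant at 0.19. These correlations run across genes, which are not independent replicates. The median absolute difference between replicates was 0.19 log units in TaVAPOE, 0.962 in the wild type and 0.999 in the mutant. Each comparison over 6 arrays involves at least 1 of these 2 discordant arrays.

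**Figure D1:**
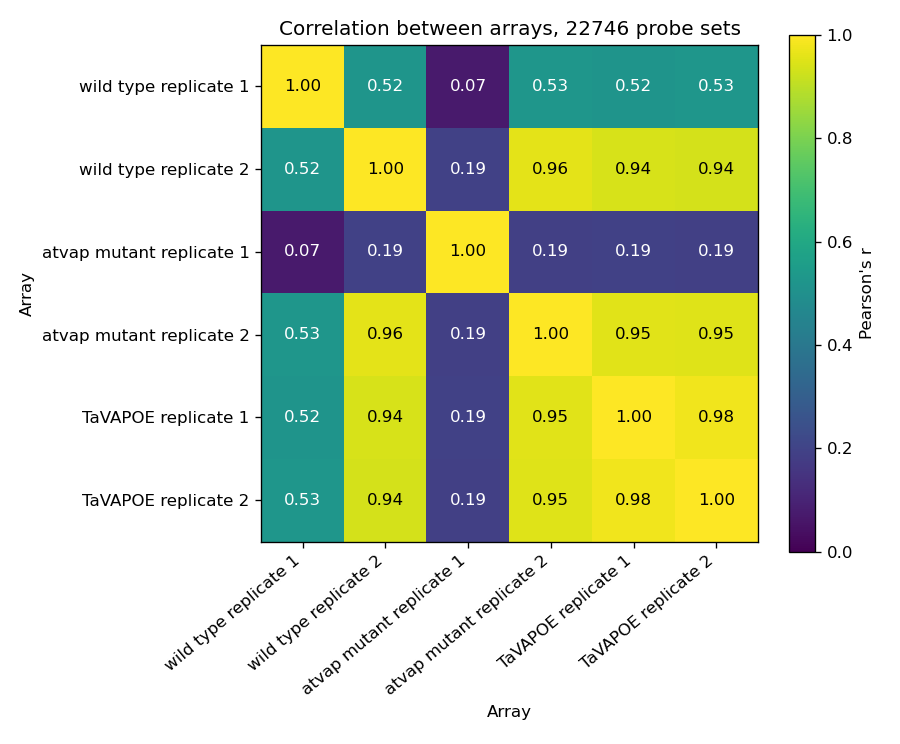
Pearson's r between each pair of the 6 arrays over the non-control probe sets, with rows and columns as arrays and colour as r. The 4 concordant arrays lie between 0.94 and 0.98, wild-type replicate 1 lies near 0.52 with them, and mutant replicate 1 lies at 0.19 or below with every array.

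**Figure D2:**
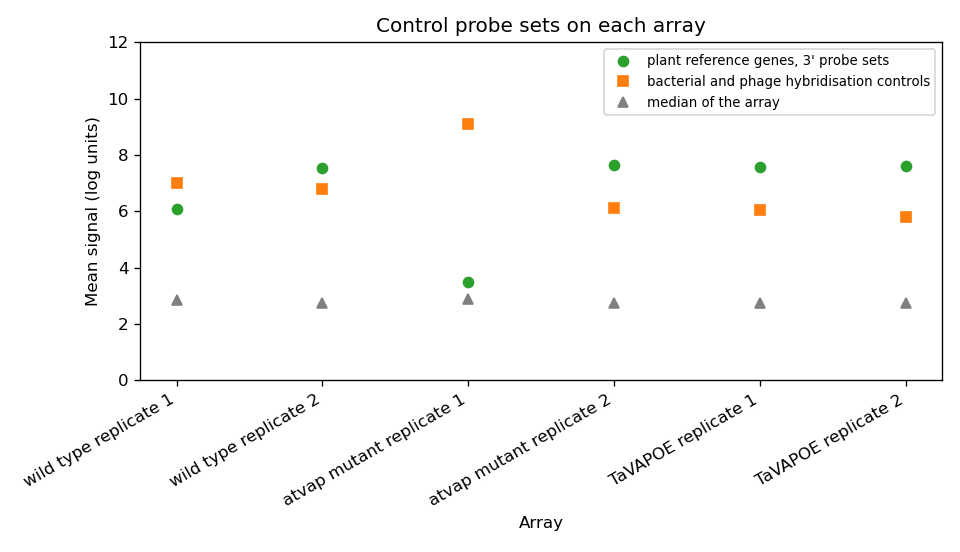
Mean signal in log units (vertical axis) of the plant reference 3' probe sets, of the hybridisation controls added to each sample and of all probe sets (median), for each array (horizontal axis); each point is 1 array. The reference genes read 3.503 on mutant replicate 1, where the hybridisation controls read 9.09.

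Of the 10 genes on the VAP27 family list, 7 were measured, and none passed the test between mutant and wild type. VAP27-1, VAP27-2 and PVA12 had no probe set with 1 gene in the annotation used here, so nothing is shown about them. The labels do not say which VAP gene is mutated, so the mutation was not checked in the data. On the concordant arrays AT5G47180 read 4.56 in the wild type, 4.39 in the mutant, and 3.38 and 3.40 in TaVAPOE. AT1G51270 read 3.69 in the wild type, 4.39 in the mutant, and 2.50 and 2.56 in TaVAPOE. The other probe set of AT1G51270 did not follow this order, at 2.05, 3.099, 2.68 and 1.36 on the same arrays. MAMI (AT5G54110) read 3.496, 3.64, 3.47 and 3.74 on the same arrays. In the fit to 6 arrays MAMI differed by -1.20 ± 0.76 log units between mutant and wild type (limma adjusted p = 0.9999), with 1.60 on mutant replicate 1. AT4G21450, AT4G05060 and AT4G00170 differed between TaVAPOE and the wild type by 0.50 ± 0.48, 0.41 ± 0.47 and 0.46 ± 0.47 log units, and AT2G23830 read at most 1.23 on any array. None of the 7 genes passed over 6 arrays in any comparison, over all probe sets or adjusted over the list alone. With the 4 concordant arrays alone AT5G47180 was 1.17 ± 0.19 log units below the wild type in TaVAPOE (difference -1.17, adjusted p = 0.0921), and AT1G51270 differed by -1.16 ± 0.19 (adjusted p = 0.0935); adjusted over the list alone, 2 of the 7 passed there. Wild-type replicate 1 did not follow, at 3.18 for AT5G47180 and 2.56 for AT1G51270, and over 6 arrays these genes differed by -0.48 ± 1.01 and -0.59 ± 0.93.

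Between the atvap mutant and the wild type, no single gene passed the test. The photosynthesis list fell, with all 5 measured members lower in the mutant by a median of -2.35 log units. LHCB4.1 differed by -3.33 ± 1.92, PSAE1 (a photosystem I subunit) by -2.50 ± 1.53, RCA by -2.35 ± 1.66 and LHCB4.3 by -0.93 ± 1.02, n = 2 arrays per group. The list passed in camera (adjusted p = 0.0104), but not with an estimated correlation (adjusted p = 0.869) or in fry (adjusted p = 0.931). It rested on mutant replicate 1: without that array the list's median difference was 0.39 (adjusted p = 0.352). Without wild-type replicate 2 it did not pass either (adjusted p = 0.838).

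Other genes stood apart with both mutant arrays on one side of both wild-type arrays, at an unadjusted p under 0.01 and an adjusted p of 0.9999. AT1G68875 read 6.37 and 4.51 in the wild type and 2.94 and 2.02 in the mutant, a difference of -2.96 ± 0.75. LBD29, a transcription factor of lateral root formation, read 3.13 and 2.82 in the wild type and 1.38 and 1.07 in the mutant (-1.75 ± 0.45). AT4G15860 differed by -1.81 ± 0.47. AT5G57720 was the only gene of this kind that was higher in the mutant (2.33 ± 0.52), at 3.59 and 2.92 against 0.80 and 1.04. For LBD29, AT4G15860 and AT5G57720 one genotype read below 1.66, the 20th percentile of all values, on both arrays; with values raised to 1.66 the differences were -1.31, -1.14 and 1.59. Comparing replicate 2 of each genotype, AT1G66850 read 6.75 in the wild type and 3.07 in the mutant, ATA27, whose name comes from an anther-expressed gene set, 3.42 and 0.90, and the defensin PDF1.2b 4.90 and 2.64. Wild-type replicate 1 read PDF1.2b at 2.15. The PDF1.2b probe set is of the class that can match several transcripts. PDF1.2, a relative of PDF1.2b, was lower on both mutant arrays by -1.41 ± 0.45 log units. Of the 2 measured jasmonate genes 1 passed adjusted over the list alone. PDF1.2 was lower in TaVAPOE as well (-1.39 ± 0.45), with the same count over the list alone. Both PDF1.2 differences are taken from the same 2 wild-type arrays. On the higher side, AT2G42950 read 2.95 in the wild type and 4.72 in the mutant, and AT1G66430 read 3.44 and 5.14. Mutant replicate 1 went the other way for both, at 2.62 and 2.67, below both wild-type arrays, and the 6-array differences were 0.55 and 0.47. The 6-array differences were also smaller for ATA27 (-1.54) and PDF1.2b (-0.90). For AT1G66850 (3.03) and ATA27 (1.96) mutant replicate 1 lay below both wild-type arrays as well. AT1G66850 had an adjusted p of 0.219 in the 4-array fit.

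The stress lists did not pass between mutant and wild type in the 6-array fit. Of 5 cold-response genes, 4 were lower, by a median over the list of -1.15 log units (adjusted p = 0.239), with ZAT10 at -1.50 ± 1.40, COR15B at -1.33 ± 1.55, COR47 at -1.15 ± 1.48 and LTI30 at -1.08 ± 1.57. Of 7 heat-shock genes 5 were higher (median 0.24, adjusted p = 0.789), with HSP17.6B at 0.85 ± 0.66 (0.66 with values raised to 1.66), HSP22.0 at -0.82 ± 0.64, HSP23.5 at -0.64 ± 0.56 and ROF2 at 0.64 ± 0.72. The 6 ER-stress genes had a median of 0.11 (adjusted p = 0.789), with DER1 at 0.90 ± 0.55, BZIP60 at -0.74 ± 1.27, BZIP28 at -0.30 ± 1.15 and ERDJ3B at 0.26 ± 1.15. The oxidative-stress genes measured were GSTU25 (-0.20 ± 0.82), UPOX (-0.09 ± 0.65) and CCS (0.02 ± 0.58), too few for a list test. The 7 auxin genes had a median of 0.07 while camera placed the list lower (adjusted p = 0.747), and the VAP27 family had an adjusted p of 0.789. Without mutant replicate 1 the cold list turned to a median of 1.09 and passed (adjusted p = 0.0346), and the ER-stress list passed as higher (adjusted p = 0.0236). The cold list passed as lower without wild-type replicate 1 (adjusted p = 0.0242) and without mutant replicate 2 (adjusted p = 0.00046), and with array quality weights, added after seeing the data (adjusted p = 0.0436). With an estimated correlation none of these calls held, with adjusted p = 0.552 for both lists without mutant replicate 1, and 0.579, 0.651 and 0.893 for the cold list in the other 3 fits. In the 4-array fit neither list passed (adjusted p = 0.630 and 0.105).

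In limma, 0 of 22746 probe sets passed between mutant and wild type, with 218 at an unadjusted p under 0.05; no other tool was run. None passed in the 4-array fit either, which had 2951 at an unadjusted p under 0.05.

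Both TaVAPOE arrays carried bright signals for several transcripts that were dim in the wild type. AT2G25510 read 9.56 and 9.45 in TaVAPOE and 3.61 and 3.02 in the wild type, 6.19 ± 0.82 log units higher (73.1-fold on base 2, adjusted p = 0.870 over 6 arrays). ECS1, a cell-wall protein, read 8.42 and 8.51 against 3.45 and 2.25 (5.61 ± 0.61, 49.0-fold, adjusted p = 0.843). AT1G66090, of the class of TIR-type immune receptor genes, was 3.83 ± 0.53 higher, AT3G28500 3.45 ± 0.82 and the receptor-like kinase gene AT1G35710 3.24 ± 0.70, all with an adjusted p of 0.870. On the lower side, AT1G68620 read 1.83 and 2.57 in TaVAPOE against 4.71 and 5.01 (-2.66 ± 0.54). AT1G44030 (-2.11 ± 0.45), AT2G17140 (-2.07 ± 0.47), AT1G64360 (-1.98 ± 0.46) and AT5G36280 (-1.94 ± 0.48) followed, with adjusted p = 0.870. The AT1G44030 probe set is of the class that can match several transcripts. AT1G44030, AT2G17140 and AT5G36280 read below 1.66 on both TaVAPOE arrays, and with values raised to 1.66 their differences were -1.16, -1.11 and -1.32. None of these passed the threshold in the 6-array fit, although both TaVAPOE arrays lay beyond both wild-type arrays for each.

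With the 4 concordant arrays, 9 probe sets passed, 7 higher and 2 lower, and 5 of them have a single gene here. Some calls of this fit were false in simulated data. That simulation gave wild-type replicate 2 the spread of the TaVAPOE pair. The median absolute difference between replicates was 0.962 log units in the wild type and 0.19 in TaVAPOE. The simulation may thus understate the share of false calls. AT2G25510 rose by 6.49 ± 0.19 log units (adjusted p = 0.0251), ECS1 by 6.21 ± 0.19 (adjusted p = 0.0251), and AT1G66090 by 4.17 ± 0.20 (adjusted p = 0.0462). AT3G44630, another TIR-type immune receptor gene, read 4.66 and 4.77 in TaVAPOE and 0.86 on wild-type replicate 2, below 1.66, so in this fit it rose by at least 3.06 log units above that single array (adjusted p = 0.0476 on the measured values); over 6 arrays it differed by 2.62. AT3G48640 fell by 5.92 log units, from 8.16 on wild-type replicate 2 to 1.97 and 2.51 in TaVAPOE (adjusted p = 0.0476). With all values raised to at least 1.66, a setting also chosen after seeing the data, none of the 9 passed (adjusted p = 0.0577 for AT2G25510 and 0.0575 for ECS1). Raising them left 4814 probe sets with no spread between the TaVAPOE arrays. Below the threshold came the thionin gene AT1G66100 (3.34 ± 0.19, adjusted p = 0.0546), AT3G48650 (3.12 ± 0.24), ZW9 (2.91 ± 0.21), the plantacyanin ARPN (2.83 ± 0.20) and, on the lower side, AT1G57650 (-3.04 ± 0.19, adjusted p = 0.0631) and PDF1.2b (-2.34 ± 0.20). Wild-type replicate 1 read 3.32 for AT3G44630, 6.51 for AT3G48640 and 4.18 for AT1G57650, and 2.15 for PDF1.2b, below both TaVAPOE arrays.

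**Figure D3:**
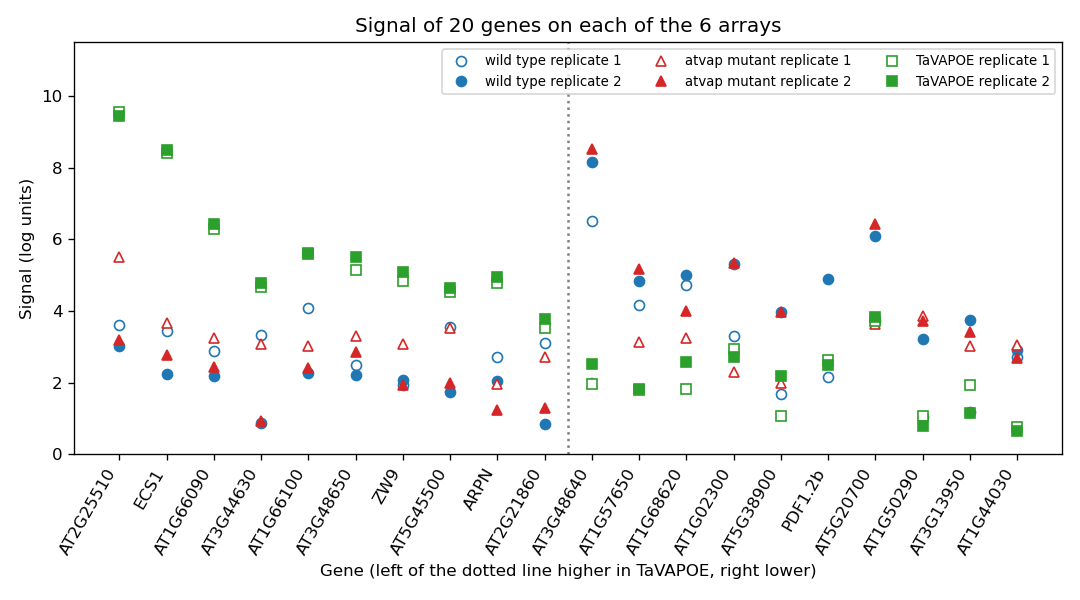
Signal in log units (vertical axis) of 10 genes higher and 10 genes lower in TaVAPOE than in the wild type in the 4-array fit (horizontal axis), on each of the 6 arrays; each symbol is 1 array. AT2G25510 read 9.56 and 9.45 on the TaVAPOE arrays and 5.50 or less on the other 4.

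Among the stress lists, ER-stress genes were higher in TaVAPOE than in the wild type in 6 of 6 members (median 1.40). The list did not pass in camera (adjusted p = 0.0527). Nor did it pass without wild-type replicate 1, without wild-type replicate 2 or without TaVAPOE replicate 1. Its members with the smallest p were BZIP60 (1.89 ± 1.27) and BZIP17, transcription factors of the unfolded protein response, CRT1B, a calreticulin (1.54 ± 1.06), and the chaperone ERDJ3B (1.58 ± 1.15). The list did pass without mutant replicate 1, without mutant replicate 2 and without TaVAPOE replicate 2 (adjusted p = 0.0229, 0.0229 and 0.0216). It also passed in the fit to the 2 groups alone (adjusted p = 0.0229), a test that leaving out 1 mutant array only repeats. With array quality weights it passed as well (adjusted p = 0.00825). With an estimated correlation the adjusted p was 0.838 over 6 arrays and 0.855 to 0.982 in these 5 fits. The median over the 4 concordant arrays was 0.34 (adjusted p = 0.0633), with BZIP60 at 0.85 ± 0.22.

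The cold-response list had a median of 0.40 over 6 arrays (adjusted p = 0.691), with ZAT10 at 0.57 ± 1.40, COR15B at 0.42 ± 1.55, COR15A at 0.39 ± 1.13 and LTI30 at 0.40 ± 1.57. Its direction turned in the 4-array fit, where the list fell by a median of 0.67 log units (-0.67, camera adjusted p = 0.0313). With an estimated correlation that fit gave an adjusted p of 0.718, and fry gave 0.170. Without wild-type replicate 1 alone, which rests on the same difference, the list did not pass (adjusted p = 0.624). In the 4-array fit COR47 and LTI30, both dehydrins, differed by -0.69 ± 0.19 and -0.70 ± 0.21, COR15B by -0.67 ± 0.19 and ZAT10 by -0.21 ± 0.19. Among these 5 genes 0 passed over all probe sets and 4 adjusted over the list alone. Wild-type replicate 1 read COR15B at 5.05 against 7.23 on replicate 2.

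CCS, the copper chaperone of superoxide dismutase, read 5.05 and 5.17 in TaVAPOE against 3.65 and 2.67 (1.95 ± 0.58, adjusted p = 0.870), and 1 of the 3 oxidative-stress genes passed adjusted over the list alone. GSTU25, below 1.66 on both TaVAPOE arrays (-1.12 ± 0.82, and -0.72 with values raised to 1.66), and UPOX (0.81 ± 0.65) did not. The heat-shock list had a median of 0.16 while camera placed it lower (adjusted p = 0.801), with HSP23.5 at -0.94 ± 0.56 (-0.55 with values raised to 1.66), HSP22.0 at -0.82 ± 0.64, HSP17.6B below 1.66 on all arrays of both genotypes and FES1A at 0.42 ± 0.46. Photosynthesis had a median of 0.05 (adjusted p = 0.691), with LHCB4.2 at 2.40 ± 1.44. Auxin had a median of -0.31 (adjusted p = 0.414), and 1 of its 7 genes, LBD29 (-1.88 ± 0.45, and -1.31 with values raised to 1.66), passed adjusted over the list alone. The VAP27 family had a median of -0.21 while camera placed it higher (adjusted p = 0.801).

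In limma, 0 probe sets passed between TaVAPOE and the wild type over 6 arrays, with 486 at an unadjusted p under 0.05; no other tool was run. With 16 added on the linear scale 2 passed, both unnamed here, and with array quality weights 3 did (AT2G25510, ECS1 and an unnamed probe set, chosen after their values were seen).

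Between TaVAPOE and the mutant no single gene passed over 6 arrays. ECS1 was 5.25 ± 0.61 log units higher in TaVAPOE (37.9-fold on base 2), AT2G25510 5.16 ± 0.82, AT1G66090 3.52 ± 0.53, ARPN 3.28 ± 0.52 and AT3G28500 3.12 ± 0.82, all with an adjusted p of 0.865 over 6 arrays. Lower were AT5G37490 (-2.39 ± 0.62), AT1G44030 (-2.16 ± 0.45), OTP86, an RNA-editing factor of plastids (-1.97 ± 0.52), and AT5G15360 (-1.75 ± 0.46), with the same adjusted p. AT5G37490, AT1G44030 and OTP86 read below 1.66 on both TaVAPOE arrays, and with values raised to 1.66 their differences were -1.65, -1.22 and -1.50. Over the 4 concordant arrays 15 probe sets passed, 12 higher and 3 lower. They included all 9 that passed against the wild type, 7 higher and 2 lower in both comparisons, which share the TaVAPOE arrays. ARPN rose by at least 3.21 log units and AT3G44630 by at least 3.06 above the single mutant array of this fit, where both read below 1.66. Mutant replicate 1 read them at 1.96 and 3.07, and over 6 arrays they differed by 3.28 and 2.72. AT1G66090 rose by 3.93 ± 0.20, and AT1G57650 fell by 3.38 and AT3G48640 by 6.29, each of the 5 with an adjusted p of 0.0450 on the measured values. With values raised to 1.66 none of the 15 passed (adjusted p = 0.124 for ECS1). Mutant replicate 1 read 1.98 for AT3G48640, as low as TaVAPOE, against 8.53 on mutant replicate 2.

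The photosynthesis list rose in TaVAPOE relative to the mutant (5 of 5 genes, median 2.49, adjusted p = 0.00189), but did not pass with an estimated correlation (adjusted p = 0.697). Among its members LHCB4.1 differed by 3.38 ± 1.92, LHCB4.2 by 3.22 ± 1.44, PSAE1 by 2.49 ± 1.53 and RCA by 2.201 ± 1.66. The cold-response list (5 of 5 genes, median 1.49) and the ER-stress list (5 of 6 genes, median 1.31) also rose (adjusted p = 0.0441 for both), with ZAT10 at 2.07 ± 1.40, COR15B at 1.75 ± 1.55, BZIP60 at 2.63 ± 1.27 and CRT1B at 1.39 ± 1.06. With an estimated correlation both lists had an adjusted p of 0.697. Without mutant replicate 1 none of the 3 lists passed, and the medians were -0.01 for photosynthesis, -0.83 for cold response and -0.05 for ER stress. Leaving out either wild-type replicate kept the medians of cold response and ER stress at 1.49 and 1.31, since no wild-type array enters this difference. Only the estimated spread changed, and these 2 lists did not pass. Nor did they with quantile normalization (adjusted p = 0.272 for cold response and 0.112 for ER stress). Over the 4 concordant arrays the cold-response list fell (median -0.83, adjusted p = 0.00311), with COR15A at -1.25 ± 0.21, COR47 at -0.88 ± 0.19 and LTI30 at -0.83 ± 0.21. With an estimated correlation that fit gave cold response an adjusted p of 0.885, and fry gave 0.400. The ER-stress list had an adjusted p of 0.831 there. CCS was 1.93 ± 0.58 higher over 6 arrays and passed adjusted over the list alone. Heat shock (median -0.10, adjusted p = 0.626, HSP17.6B at -1.29 ± 0.66, or -0.66 with values raised to 1.66), auxin (median -0.28, adjusted p = 0.593) and the VAP27 family (median -0.06, placed higher by camera, adjusted p = 0.593) did not pass. In limma, 0 probe sets passed over 6 arrays, with 297 at an unadjusted p under 0.05, again fewer than the 5% that unchanged probe sets would give. With 16 added, 1 unnamed probe set passed. No other tool was run.

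The design also asks whether the mutant and the overexpressor moved genes in opposite directions. Their differences from the wild type correlated at Pearson r = 0.30 across 22746 probe sets (Spearman rho 0.30), and 61.1% had the same sign. Unchanged groups sharing the same wild-type arrays gave r = 0.50 and 66.6% in simulation. The covariance was 0.17 against 0.30 simulated, where the simulation gave every array the pooled spread, that of the discordant arrays included. In the 4-array fit r was 0.57 against 0.58 simulated, and the covariance 0.15 against 0.04, where the simulation gave wild-type replicate 2 the spread of the TaVAPOE pair. The wild-type arrays are too few to split, so part of any excess may come from the shared controls. The value rested on single arrays: r was -0.21 without mutant replicate 2, 0.83 without mutant replicate 1, 0.77 without wild-type replicate 2 and 0.18 without wild-type replicate 1.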

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

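The tests in this part were chosen after the values of the arrays had been seen. The bacterial and phage hybridisation controls, which lie outside the gene comparisons, averaged 9.09 log units on mutant replicate 1, above both wild-type arrays (6.996 and 6.79). On the other mutant array they averaged 6.11.

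Mutant replicate 1 and wild-type replicate 1 stood apart from the other 4 arrays. A swap of their labels with each other is argued against as the reason, since wild-type replicate 2 and mutant replicate 2 correlated at 0.957, while wild-type replicate 1 reached only 0.521 and 0.525 with them and mutant replicate 1 only 0.193 and 0.190. Little labelled plant target on the array is a candidate explanation for both. The plant reference genes averaged 3.503 on mutant replicate 1 and 6.09 on wild-type replicate 1, below the 7.54 to 7.65 of the others. The hybridisation controls were not lower on average. On wild-type replicate 1 single controls went both ways. There r2-Ec-bioC-3 read 5.22, against 6.23 to 7.59 on the 4 concordant arrays, and BioB-3 read 6.03, against 1.11 to 3.13. The controls thus bear less clearly on wild-type replicate 1 than on mutant replicate 1. Degraded RNA cannot be told apart for wild-type replicate 1, whose 3' minus 5' difference of 2.46 lay above the others' highest value of 2.16 by less than their range. Whether their labels were swapped as well is not shown by these correlations, and a mistaken sample from outside the series and a biological difference between the plants stay open, as untested.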

How the results depend on the processing

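The 4-array fit, its own alternatives, the array weights and an estimated correlation in other fits were chosen after seeing the data. The other settings had been fixed beforehand, and the cause was not tested where a value changed. In simulation with variances drawn from the fitted prior, the 6-array fit recovered 0% of changes of 4 log units in each comparison. A count of 0, or its staying at 0, thus does not show that no gene changed. Calls of 0 probe sets in limma stayed at 0 under the other settings, leave-one-out included (0 to 0 in each comparison). Exceptions were 16 added on the linear scale (2 for TaVAPOE against wild type, 1 against mutant), array weights (3 against wild type) and the 4-array fit (9 and 15, but 0 in all 3 comparisons with values raised to the 20th percentile). Array weights came out equal within each pair, so they weigh genotypes, not single arrays. A threshold of unadjusted p under 0.05 with a 2-fold difference gave 218 probe sets for mutant against wild type, 486 for TaVAPOE against wild type and 297 for TaVAPOE against mutant. The 4-array fit at an unadjusted p under 0.01 gave 810, 1779 and 1092.

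Lists called for mutant against wild type numbered 1, and 2 with the replicate block or array weights, 0 in the 4-array fit, with an estimated correlation and in fry, and 0 to 2 leaving out single arrays. For TaVAPOE against wild type they numbered 0, but 1 with the replicate block, in the fit to the 2 groups alone, in the 4-array fit and with array weights, and 0 to 1 leaving out single arrays. For TaVAPOE against mutant they numbered 3, but 1 with the 40th-percentile filter, quantile normalization, median centring, the fit to the 2 groups alone, the floor, 16 added and the 4-array fit, 0 with an estimated correlation and in fry, and 0 to 3 leaving out single arrays. The 4-array fit called 0 lists in each comparison with an estimated correlation or in fry, as did the fits that leave out 1 array, the fit to the 2 groups and array weights with an estimated correlation. With values raised to the 20th percentile it called 0 for mutant against wild type, 2 for TaVAPOE against wild type (cold response and ER stress) and 1 for TaVAPOE against mutant. The filter left 4 lists with enough genes. The correlation ran from -0.21 to 0.83 leaving out single arrays.

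Medians of lists turned when mutant replicate 1 was left out. For mutant against wild type they became 1.09 (cold response) and 0.39 (photosynthesis), and for TaVAPOE against mutant -0.833 (cold response), -0.0541 (ER stress) and -0.0136 (photosynthesis), as in the 4-array fit. Leaving out mutant replicate 2 gave the other end: -3.40 and -5.01 for mutant against wild type, and 3.81, 2.67 and 5.00 for TaVAPOE against mutant, in the same order of lists. The 4-array fit also turned cold response in TaVAPOE against wild type to -0.67. Leaving an array out leaves a lone sample, which is assumed to vary like the other groups. Single genes kept their direction and side of the threshold in 2074 of 2159 values from the fixed settings, and the other 85 changed sign without passing.

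The replicate numbers share only a number: deviations of same-numbered arrays correlated at 0.58 between wild type and mutant, where both first replicates are the discordant ones, and at 0.01 and 0.09 with TaVAPOE. The replicate block kept the probe-set calls at 0 in all 3 comparisons. In camera it added cold response as lower in mutant against wild type (adjusted p = 0.0459) and ER stress as higher in TaVAPOE against wild type (adjusted p = 0.00733). Without the block, camera with an estimated correlation gave these 2 lists adjusted p = 0.869 and 0.838. The block was not run with an estimated correlation. No detection calls were used here; the 99th percentile of signal was 4.88 on mutant replicate 1 and 5.85 on wild-type replicate 1 against 7.68 to 7.80 elsewhere, which limits what both can show.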

Other observations

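The tests in this part were chosen after the values they concern had been seen, and the 4 concordant arrays are wild-type replicate 2, mutant replicate 2 and both TaVAPOE arrays. Genes of lists too short to test also stood apart on these arrays. EXPA4, an expansin that loosens cell walls, read 2.096 in the wild type, 2.53 in the mutant and 4.34 and 4.19 in TaVAPOE, and XTH18, a cell-wall xyloglucan enzyme, 6.11, 6.52, and 4.92 and 4.86. BCAT4, of methionine-derived glucosinolate synthesis, read 4.39, 5.32, and 5.69 and 5.64. KEU, a vesicle-fusion regulator, read 4.99, 5.35, and 4.05 and 4.18. For KEU the discordant arrays read lower than TaVAPOE, at 2.70 (wild type) and 3.66 (mutant), and its difference between TaVAPOE and the wild type turned from -0.88 in the 4-array fit to 0.27 over 6 arrays. Mutant replicate 1 likewise read XTH18 at 2.91. In the 4-array fit EXPA4 differed from the wild type by 2.17 ± 0.20 in TaVAPOE (limma adjusted p = 0.0777) and XTH18 by -1.22 ± 0.19 (adjusted p = 0.0915), so neither passed.

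Among root genes, PYK10, an abundant beta-glucosidase of root ER bodies, read 2.78 in the wild type, 2.87 in the mutant and 3.74 and 3.99 in TaVAPOE, and the root-hair expansins EXPA7 and EXPA18 read 3.12 or less on the concordant arrays. EXPA7 read 3.79 on mutant replicate 1. Plastid-encoded transcripts, a group added after seeing the data, were mostly higher on mutant replicate 2 than on wild-type replicate 2 (55 of 69 genes, median 0.33), including 14 of 15 psb genes of photosystem II. That count sets 1 array against 1 array; over 6 arrays 35 were higher and 34 lower in the mutant (median 0.0084). None of the 69 passed in either fit.

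Both TaVAPOE arrays lay at least 2 log units outside wild-type replicate 2 and mutant replicate 2 for 52 probe sets, 36 higher and 16 lower. The other pairings of these 4 arrays gave 0 such probe sets, but each splits the TaVAPOE replicates, which correlated at 0.98. That 0 follows from how close these replicates are and says nothing about the genotype. All 36 were also higher than on wild-type replicate 1, but of the 16 lower only 12 were lower than on that array. An effect limited to genes beside one insertion site is argued against, since the 23 nuclear genes named among them lie on 5 chromosomes. The fullest holds 47.8% of them but 25.8% of all measured genes, so the set is not spread evenly. The rest of the 52 probe sets were not placed. A different parental line is a hypothesis that stays open: 2 pairs of neighbouring measured genes were in the set, AT1G66090 with AT1G66100 and AT3G48640 with AT3G48650, of which the second pair went in opposite directions (AT3G48640 lower and AT3G48650 higher in TaVAPOE), against a median of 0 in 10000 random sets (one-sided permutation p = 0.0004). That test was made on the set in which the pairs had been noticed. Neighbours that move together, as the first pair did, can also share regulation, and an effect of TaVAP or a separate handling of the TaVAPOE samples was not tested.

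ATA27 and AT1G66850 were lower on mutant replicate 2 than on the other concordant arrays. All samples are labelled as 5-day-old plants, so flower tissue could only be a contaminant of the other samples. These values do not tell such a contaminant apart from a difference between the genotypes. Of 6 measured anther genes 5 read lower on mutant replicate 2 than on wild-type replicate 2, and 3 read lower than on each other concordant array (one-sided exact binomial p = 0.169). The 11 other floral and pollen genes measured went both ways, 6 lower and 5 higher on mutant replicate 2 than on wild-type replicate 2. A9, an abundant anther transcript, read 2.93 on wild-type replicate 2, 1.38 on mutant replicate 2 and 2.96 and 2.40 in TaVAPOE, and SHT 2.64, 0.89, and 1.51 and 1.40. None of the 6 lay above the 75th percentile of wild-type replicate 2, so they are too dim to exclude a small share of flower tissue. Mutant replicate 1, a discordant array, also read ATA27 (1.96) and AT1G66850 (3.03) below both wild-type arrays. Among the concordant arrays both readings rest on 1 mutant array.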
